A study of Mus musculus with 9 samples.

How the data were processed

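Gene expression was measured in macrophages sorted from the lungs of female C57/BL6 mice aged 8 weeks, on 9 single-colour Illumina beadchip arrays. Per the labels, cells were sorted by the surface proteins SiglecF and CD11b and lysed at once, RNA was isolated with a column kit, amplified as cDNA by an isothermal whole-transcriptome method and labelled with biotin. The labels give 3 groups of 3 arrays. Pparg-deficient cells came from Pparg-/-.LysMCre mice, in which a Cre recombinase is driven by the LysM promoter. Homozygous wild type cells came from mice of the same genotype label and are called wild type by their cell type label. Heterozygous cells came from Pparg-/+.LysMCre mice and are also called wild type. How wild type cells were told from deficient cells in mice of 1 genotype is not given in the sources used here beyond the sort. The titles number the samples of each group from 1 to 3, but nothing says whether a number stands for a separate mouse, so p-values measure only the spread between these samples, which may be technical.

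The deposited table holds an intensity per probe on a linear scale, not normalized per the file headers, beside a detection p-value per probe and array, which is deposited with no stated method. The detection p-values fall with the signal in broad terms but not in strict order. On deficient replicate 1, for example, signals of 292.6 and 300.9 had a detection p of 4.2e-18 and 3.6e-11. They reach values too small for a rank among negative control probes, so they come from a model. The authors also deposited a normalized intensity table of the same arrays, whose method is not given in the sources used here. Each of its columns is a nearly monotone function of the signal of the same array (rank correlations from 0.99966 to 0.999999) with medians from 193.1 to 203.2, and it has no sign or centring to settle. No columns beyond those of the 9 arrays were present. No genome build is named, so no coordinates are printed.

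From the intensities, background was corrected by the normexp method of limma 3.58.1 (R 4.3.3) with negative control statistics inferred from the detection p-values and an offset of 16, followed by quantile normalization between arrays and log2. The inference treats the detection p-values as ranks among negative control probes, which they are not. The counts under other background corrections are therefore given with the alternatives. Probes with a detection p under 0.05 on at least 3 of the 9 arrays were kept, 21946 of 46237. The platform annotation gave 35784 probes 1 gene symbol, 0 several and 10453 none. Symbols were updated through gene identifiers (28620 probes) or accessions (2637 probes) in a RefSeq table of assembly GRCm38.p6, and 4527 kept the annotation's symbol. For each gene the passing probe with the highest mean log2 signal was used, which left 12246 genes. Of these, 3579 had several passing probes, and where another probe of a named gene differed in sign or in its call against both controls, that is said with the gene. The 4669 passing probes without a symbol are not part of the gene counts.

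A linear model with 1 mean per group was fitted over all 9 arrays with lmFit and eBayes, so that the 3 groups share 1 estimate of the spread. The 4 comparisons were Pparg-deficient cells against the mean of both control groups, against heterozygous cells, against homozygous wild type cells, and homozygous wild type against heterozygous cells. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. A group in which all 3 arrays had a detection p of 0.05 or more has only a bound. Its fold is then written "at least", as the brighter group's mean against the mean of, per array, the higher of the probe's own value and the lowest signal among probes above background. All other differences are limma's log2 differences with their standard error (SE). Before the data were examined, 32 gene lists were fixed, of which the 31 with at least 5 measured genes were tested with camera at a preset correlation of 0.01 and adjusted over the lists of each comparison, and again with an estimated correlation and with fry.

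The genes named were set by a rule fixed at the same time. It takes Pparg and Lyz2 (the gene whose promoter drives the Cre) in each comparison, and the 10 largest increases and decreases past the threshold against both controls whose deficient arrays all lie outside the 6 control arrays. It takes the 3 largest each way against each control group, up to 5 each way between the controls, and in a described list up to 4 members with the smallest p plus up to 2 of the opposing sign. Predicted genes and clones were passed over. Where a gene is named outside this rule, the text says so.

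The fit was tested on simulated arrays made from the real means and limma's moderated spreads of the 12246 genes, with 200 genes changed in the deficient group. The noise was normal and held no array effects, so recovery in the real data may be lower. For Pparg-deficient cells against both controls it recovered 9% of genes changed 2-fold, 77.6% of those changed 4-fold and 100% of those changed 8-fold, with 4 false calls. Recovery was 4.5%, 59.7% and 95.5% against heterozygous cells, and 6%, 62.7% and 95.5% against homozygous wild type cells, with 3 false calls each. A raised gene list was called by all 3 list tests, and of 24 other lists without shared genes camera called 0 against both controls and 1 between the controls, where nothing was changed. The simulated genes varied independently of each other. The simulation therefore does not show how often lists are called falsely where genes vary together. Alternatives were other background corrections, scalings, filters, probe rules and model settings, the authors' normalized table, the replicate number as a block, and leaving out each array in turn. A covariate for the background level of each array, and leaving out arrays in the list tests, were added after seeing the data. The slide could not be a block for comparisons with the deficient group, since the 3 deficient arrays lie on 1 slide and the 6 control arrays on another. Slide and group cannot be told apart there, and the control comparison lies within 1 slide.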

Results

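Alveolar macrophages are the resident phagocytes of the lung air spaces, and PPARg, encoded by Pparg, is a lipid-activated nuclear receptor that these cells express. The series asked how gene expression differs in alveolar macrophages that lack Pparg, with its title naming proinflammatory responses. Macrophages labelled Pparg-deficient were compared with 2 control groups labelled wild type, 1 from mice of the same homozygous genotype and 1 from heterozygous mice, with 3 arrays each. The sample titles call the deficient cells "int pop" and both control groups "Mph", without explaining the first, so the deficient group was titled as another population and that difference goes with every comparison of it below. The arrays' median raw signal ran from 145 to 290.3, with 146.2, 159.6 and 184.2 in the deficient group, 145, 241.7 and 209.9 in the homozygous wild type group and 198.4, 217 and 290.3 in the heterozygous group. Between 37.8% and 42.5% of probes per array were above background. Log2 signals over genes correlated between arrays of 1 group at a median of 0.864 (9 pairs) and between groups at 0.837 (27 pairs). No pair of arrays held identical signals. The number of arrays limits the precision of each value below.

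Pparg itself was lowest in the deficient group. Its brightest probe read 7.52 ± 0.27 (SD, n = 3, log2 signal) in deficient cells, 9.00 ± 0.80 in homozygous wild type cells and 9.45 ± 0.09 in heterozygous cells. All 3 deficient arrays lay below all 6 control arrays, a log2 difference of -1.70 (SE 0.335). An exact two-sided permutation test gave p = 0.0119, the smallest that 84 choices of 3 arrays allow. In the limma fit over all genes the adjusted p was 0.0592, so Pparg was not called against both controls. It was not called against heterozygous cells (-1.93, limma adjusted p = 0.0538) or homozygous wild type cells (-1.48, adjusted p = 0.288) either; exact permutation tests of 3 against 3 arrays gave p = 0.1 for both, the smallest they allow, and between the control groups the difference was -0.46 (adjusted p = 0.869). Without homozygous wild type replicate 3, the lowest control array at 8.13, the difference from both controls was -1.92 with an adjusted p of 0.0126; over all alternatives it ran from 0.00488 to 0.257. The other passing Pparg probes differed by -0.82 and -1.58 (adjusted p = 0.373 and 0.28 over all probes), and at both of them deficient and homozygous wild type arrays overlapped. Where the probes lie relative to the deleted exons is not known, so these values do not check the labels. Lyz2 did not pass the probe filter, and its 3 probes were above background on heterozygous arrays only.

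**Figure D1:**
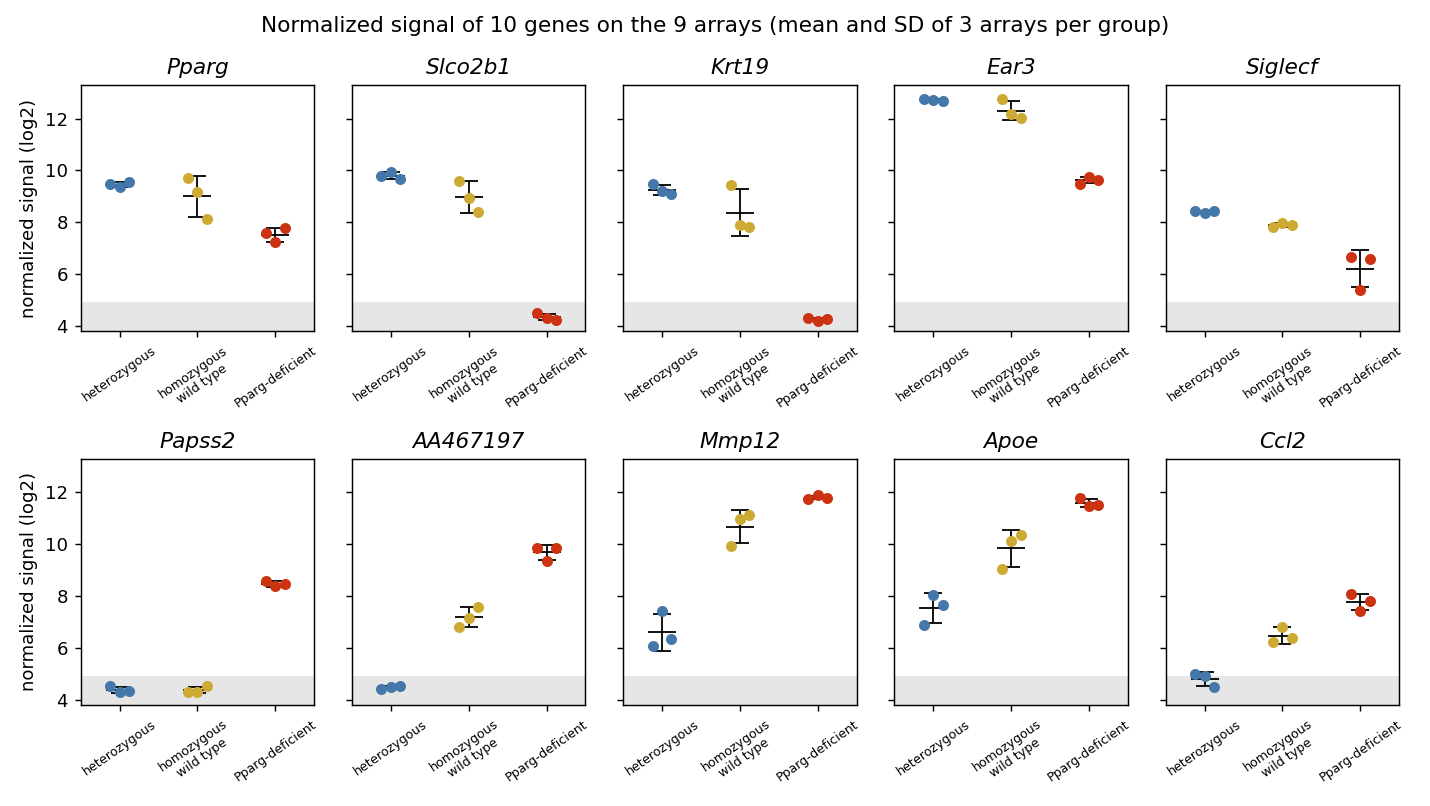
Normalized log2 signal (y axis) of 10 genes in the 3 groups (x axis), with 1 point per array and the mean and SD of 3 arrays in black; the grey band ends at the mean, over the arrays, of the lowest signal among probes above background. Slco2b1 and Krt19 lie in the band on all 3 deficient arrays, and Papss2 lies in it on all 6 control arrays.

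Against both control groups, the genes of this paragraph were called whichever array was left out, where they still passed the filter. Slco2b1, an organic anion transporter, was at least 23.3-fold lower and Krt19, a keratin, at least 15.7-fold lower (limma adjusted p = 7.44e-05 and 0.000566). Vstm2a was at least 8.75-fold lower, and Ffar2, a receptor for short-chain fatty acids, at least 6.90-fold lower. Ear3, of the eosinophil-associated ribonuclease family, fell 7.40-fold, from 12.71 ± 0.04 in heterozygous and 12.31 ± 0.38 in homozygous wild type cells to 9.63 ± 0.13 (SD, n = 3 each), and its second probe differed by -1.78 (log2); members of this family have similar sequences, so a probe may read several. AA467197 was at least 12.5-fold higher, Tnfsf9, the ligand of the costimulatory receptor 4-1BB, at least 13-fold, Tns3 at least 8.76-fold, Anpep, an ectopeptidase of myeloid cells, at least 7.29-fold and Csf1, a macrophage growth factor, at least 6.55-fold higher. Mmp12, macrophage elastase, rose 8.98-fold to 11.81 ± 0.07 against the mean of 2 control groups that differed widely from each other in this gene, as given below. In all, 94 of 12246 genes were called, 70 higher and 24 lower (1563 at an unadjusted p under 0.05). Of the 70 and 24, 63 and 21 were also called against heterozygous cells alone, but only 16 and 6 against homozygous wild type cells alone. For 47 of the 94, at least 1 group was below background. With both controls fitted as 1 group, Tnfsf9, AA467197 and Mmp12 were not called (adjusted p = 0.124, 0.0635 and 0.301), nor were 11 other genes named for this comparison (0.0546 to 0.419).

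Most of the remaining largest changes lost the call without individual arrays, and apart from Papss2 they kept their direction and most of their size. Pmp22 (13.1-fold higher), C1qb, a chain of the complement starter C1q (at least 8.78-fold), Vnn3, a pantetheinase (at least 8.30-fold), and Acaa1b, a peroxisomal thiolase (21.6-fold lower), lost their calls without deficient replicate 1 and in no other fit that left out an array, with limma adjusted p of 0.0719, 0.0685, 0.0719 and 0.065 and log2 differences of 3.43, 2.90, 3.09 and -4.32 there (3.72, 3.50, 3.28 and -4.43 with all arrays). Papss2, which makes the sulphate donor, was at least 12-fold higher by its brightest probe, but its second probe differed by -0.25 and was the one used, and not called, without any 1 deficient array. Gas7 (14.0-fold) and Lat2 (14.0-fold) were higher, with second probes at 2.39 and 1.24 (log2) that did not pass. Fcgr4, an Fc receptor (11-fold), Syne2 (at least 7.77-fold, with a second probe at -2.18 and an adjusted p of 0.0562), Cidec, a lipid droplet protein (at least 8.02-fold), and Cyb561a3 (7.89-fold) were lower. Gas7, Lat2, Fcgr4, Syne2 and Cidec each lost the call without any of at least 3 of the 9 arrays, at log2 differences of 3.41 to 4.12, 3.54 to 3.93, -3.49 to -3.45, -3.54 to -3.26 and -3.59 to -3.36 (3.81, 3.8, -3.46, -3.45 and -3.43 with all arrays), while Cyb561a3 kept it. Of the 35 called genes named for this comparison, 14 were called whichever array was left out, where they still passed the filter. Among the 14, Anpep, C3ar1 and Asns passed it in only 6 of the 9 fits, so their dependence on the other arrays was not tested. The total of 94 fell to 22 without deficient replicate 1, 33 without deficient replicate 2, and 61, 62 and 55 without heterozygous replicates 1, 2 and 3. Without normalization between arrays, which left a median log2 difference of -0.29 over all genes, the split was 52 higher and 40 lower.

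Proinflammatory cytokines and chemokines were the gene list with the smallest camera p at the preset correlation. Of 26 measured members 3 rose (Tnfsf9, Ccl2 and Csf1) and 0 fell, 23 had a positive difference, and the median was 0.58. Adjusted over the list alone, 11 were higher and 1 was lower. Ccl2, a monocyte attractant, was at least 4.12-fold higher in deficient cells (limma adjusted p = 0.00595), with an adjusted p of 0.0548 without deficient replicate 1 and 0.117 with both controls fitted as 1 group. Ptgs2 differed by 2.61 (SE 0.50, adjusted p = 0.0548). Nos2 differed by -1.19 (adjusted p = 0.288) and by 0.03 at its second probe. The list was called by camera (adjusted p = 2.79e-11), with an adjusted p = 0.215 with an estimated correlation. NF-kB feedback genes were called higher too (adjusted p = 0.000122, and adjusted p = 0.246 with an estimated correlation). Of their 20 measured members 1 rose, Birc3, an inhibitor of apoptosis (at least 3.28-fold, not called without any 1 deficient array), Nfkb1 differed by 1.43 and Socs3 by 2.17 (limma adjusted p = 0.161 and 0.229), and adjusted over the list alone 1 was higher. Immediate early and heat shock genes, which also mark tissue dissociation, were called higher (adjusted p = 5.73e-05, and 0.215 as adjusted p with an estimated correlation). Of their 24 measured members 1 rose, Ier3 (2.34-fold), Hspa1a differed by 1.41 and Jun by 1.01 without passing, and adjusted over the list alone 5 were higher. The call of Ier3 (adjusted p = 0.0476) ended whichever array was left out.

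Matrix remodelling genes were called higher (camera adjusted p = 0.00243, and adjusted p = 0.215 with an estimated correlation), with Mmp12 and Mmp8, a collagenase also stored by neutrophils, the 2 of 17 members that rose and 6 higher adjusted over the list alone. Mmp8 was at least 3.10-fold higher but lost the call without any 1 of 7 arrays, and Plau, urokinase, differed by 1.44 (limma adjusted p = 0.0572). Markers of monocytes and interstitial macrophages were called higher (adjusted p = 0.00994, and adjusted p = 0.215 with an estimated correlation). Of their 17 measured members 2 rose (Mmp12 and C1qb), 1 fell (Fcgr4), and Csf1r, the receptor of Csf1, differed by 1.92 (limma adjusted p = 0.0569). Adjusted over the list alone, 5 were higher and 1 lower. Of 15 complement and Fc receptor genes, C1qb and C3ar1, the receptor of the C3a peptide (at least 5.08-fold), rose and Fcgr4 fell, and the list was called higher (adjusted p = 0.0231, and adjusted p = 0.257 with an estimated correlation; 4 higher and 1 lower adjusted over the list alone). The monocyte list was not called without deficient replicate 3 (adjusted p = 0.0534), nor the complement list without deficient replicates 1, 2 or 3 (0.609, 0.119 and 0.408). Against homozygous wild type cells alone, camera called neither of these lists (adjusted p = 0.099 and 0.188) nor the matrix remodelling list. In that comparison 0 members of the monocyte list were called. Other lists called higher were those of cholesterol synthesis (median 0.50, camera adjusted p = 0.00994), lysosomal genes (0.22, adjusted p = 0.015), macrophage transcription factors (0.19, adjusted p = 0.0174) and MHC class II presentation (0.47, adjusted p = 0.0321), in which 0 members passed over all genes. With an estimated correlation these 4 lists had adjusted p from 0.215 to 0.257, and fry did not call cholesterol synthesis or MHC class II presentation (adjusted p = 0.0746 and 0.155). Irf4 among the transcription factors differed by 2.16 and the costimulator Cd86 by 1.18 (limma adjusted p = 0.0556 and 0.125). Ribosomal protein genes were called too (median 0.10, camera adjusted p = 0.0174, and adjusted p = 0.415 with an estimated correlation), with 1 of 21 members called, Rplp0 at least 4.2-fold higher. Without deficient replicate 1 the lists of lysosomal genes, macrophage transcription factors and MHC class II presentation were not called (0.0565, 0.0565 and 0.15). The transcription factors also lost the call without deficient replicate 2 or 3 or heterozygous replicate 3 (0.111, 0.0606 and 0.0711), and MHC class II presentation without deficient replicate 2, homozygous wild type replicate 2 or heterozygous replicate 3 (0.0815, 0.065 and 0.131). With the background level of each array as a covariate, 6 of the 13 lists called were not called: cholesterol synthesis, NF-kB feedback, MHC class II presentation, complement and Fc receptors, lysosome and macrophage transcription factors (0.297, 0.0513, 0.768, 0.0946, 0.137 and 0.375). The direction of MHC class II presentation was then lower.

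Cell cycle genes and genes of fatty acid oxidation were the 2 lists called lower against both controls. The cell cycle list was not called against homozygous wild type cells alone. Of 21 cell cycle genes 1 fell, Rrm2, a subunit of ribonucleotide reductase (3.14-fold), 18 had a negative difference and the median was -0.58 (camera adjusted p = 0.00234, and adjusted p = 0.215 with an estimated correlation). Adjusted over the list alone 2 were lower. Mcm5, Mcm6 and Mki67 differed by -2.53, -0.88 and -1.14 without passing (-0.35 and -0.13 at second probes of Mcm6 and Mki67), the second probe of Rrm2 did not pass (-1.45, adjusted p = 0.17), and the call of Rrm2 (limma adjusted p = 0.0406) ended whichever array was left out. Of 21 genes of beta oxidation and peroxisomes Acaa1b fell, 15 had a negative difference and the median was -0.43 (camera adjusted p = 0.015, and adjusted p = 0.257 with an estimated correlation). Ech1 and Etfb differed by -1.30 and -0.56 without passing, and adjusted over the list alone 2 were lower. This call ended when all probes of a gene were averaged (adjusted p = 0.0865), with every probe tested (0.228), and without homozygous wild type replicate 1 or deficient replicate 3 (0.0935 and 0.0914). In the list of lipid handling genes linked to PPARg, Acaa1b and Cidec fell, Lpl and Dgat2 differed by -0.67 and -1.14 without passing, and camera did not call the 17 genes (adjusted p = 0.107), while fry, which tests for movement in 1 direction without comparing to other genes, did (adjusted p = 0.00924). In the alveolar macrophage identity list Krt19, Siglecf and Marco, a scavenger receptor, were the 3 of 24 members that fell, and adjusted over the list alone 5 were lower and 2 higher. Marco fell 5.49-fold and Siglecf 3.82-fold. Against homozygous wild type cells alone, Krt19 was the 1 of the 24 members called, and 0 of the 17 lipid handling genes were called. The cells were sorted by the SiglecF protein, so its transcript is no finding between the groups. Krt79 differed by -1.42 and Slc7a2 by 0.95 (limma adjusted p = 0.069 and 0.117). The list was not called by camera (adjusted p = 0.114) and was called by fry (adjusted p = 0.00645). Marco and Siglecf each lost the call without any 1 of 5 arrays.

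**Figure D2:**
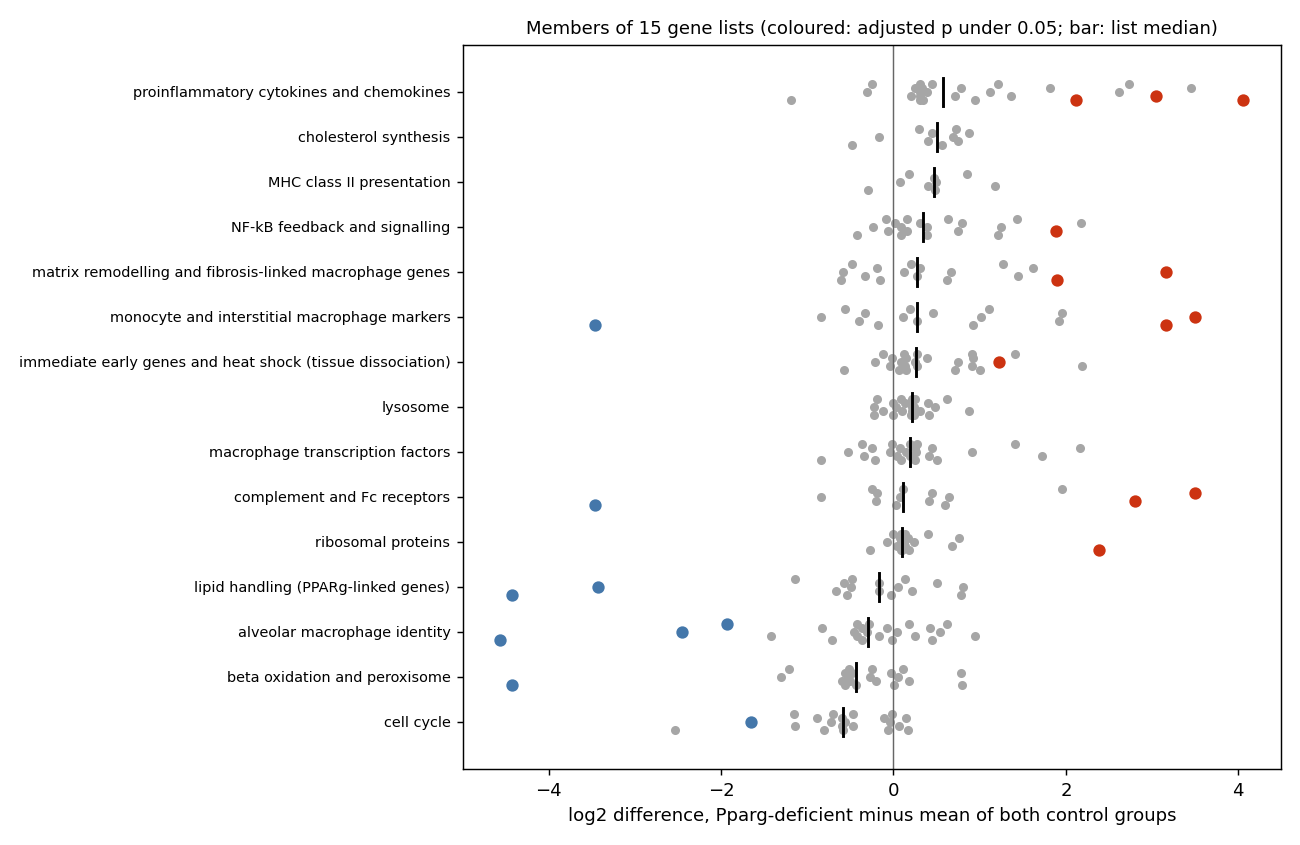
Log2 difference between Pparg-deficient cells and both controls (x axis) for each measured member of 15 gene lists (y axis), 13 called by camera plus lipid handling and alveolar macrophage identity. Red and blue points are genes called higher or lower, grey points did not pass, and black bars mark list medians, from -0.58 for cell cycle genes to 0.58 for proinflammatory cytokines and chemokines.

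Markers of other cell types were compared in the same way. Of 12 lung epithelial markers 1 rose, Hopx, a homeodomain protein of flat alveolar epithelium (4.43-fold, adjusted p = 0.0639 without deficient replicate 1), and camera did not call the list (adjusted p = 0.0741), while fry called it higher (adjusted p = 0.00718). Of 7 neutrophil markers Mmp8 rose and S100a8 differed by 1.33 (limma adjusted p = 0.137), but the other 5 had a negative difference and the median was -0.41. Adjusted over the list alone 2 were higher and 2 lower, and the list was not called by camera (adjusted p = 0.561). Camera called none of the lists of eosinophil (adjusted p = 0.561), dendritic cell (0.497), T, B and NK cell (0.157) and endothelial and stromal markers (0.199), in which 0 members passed over all genes; the medians and means of the eosinophil list (-0.01 and 0.11) and the dendritic cell list (-0.04 and 0.22) differed in sign. Fry called the T, B and NK cell markers lower (adjusted p = 0.00619), with all 6 measured members negative. Only 4 of 14 red cell and platelet markers were measured, too few to test, and 0 of them passed.

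Compared with heterozygous cells alone, 6 genes led the changes. Tnfsf9 was at least 32.2-fold higher and AA467197 at least 27.6-fold higher in deficient cells, and Lat2 was 56.4-fold higher by its brighter probe (1.44 on the log2 scale by the other). Slco2b1 was at least 31.0-fold lower, Krt19 at least 21.3-fold lower and Acaa1b 30.7-fold lower. The limma fit called 129 genes, 96 higher and 33 lower. All 6 named genes were called whichever array was left out. The count was 44, 50, 82, 75 and 60 without deficient replicates 1 and 2 and heterozygous replicates 1, 2 and 3. Camera called 12 lists, 10 higher and 2 lower, led by proinflammatory cytokines (adjusted p = 2.43e-11) and, lower, cell cycle genes (adjusted p = 0.000144), and the smallest adjusted p with an estimated correlation was 0.104.

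Compared with wild type cells from mice of the same genotype, fewer genes passed. Papss2 was at least 12.2-fold higher by its brightest probe, with -0.24 at the other probe. Vnn3 was at least 8.42-fold higher and Wtip at least 7.29-fold. Slco2b1 was at least 17.5-fold lower, Krt19 at least 11.5-fold lower and Vstm2a at least 9.03-fold lower. The limma fit, which does not pair arrays that share a title name, called 24 genes, 18 higher and 6 lower. The 3 genes named as lower were called whichever array was left out. Vnn3 and Wtip lost the call without any of at least 5 arrays, and Papss2 without any deficient array. The count was 7 without deficient replicate 1 and 11 without deficient replicate 2. Without normalization between arrays the split was 11 higher and 9 lower, and with median scaling 15 and 9. Camera called 7 lists, among them proinflammatory cytokines (adjusted p = 7.6e-08) and cholesterol synthesis (adjusted p = 6.8e-05), both higher. Beta oxidation was lower (adjusted p = 0.0255, and 0.317 and 0.113 without homozygous wild type replicate 1 and deficient replicate 3). The others were NF-kB feedback, immediate early, MHC class II presentation and unfolded protein response genes, all higher. Of these, all but immediate early genes lost the call without deficient replicate 1. The smallest adjusted p with an estimated correlation was 0.349. The monocyte, complement, lysosomal, transcription factor, matrix remodelling, cell cycle and ribosomal lists, called against both controls, were not called here.

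The comparisons with each control share the 3 deficient arrays. Of the genes called higher, 14 were called in both (0.141 expected of independent lists), and of those called lower, 6 (0.0162 expected). Across genes, which are not independent replicates, the log2 differences correlated at 0.674, against 0.499 in 100 simulations of unchanged groups. Their covariance was 0.275 against a simulated 0.0988. The expected overlaps take the lists as independent, so part of their excess may come from sharing these arrays. The simulations share the deficient arrays too, but only with noise independent between genes. The deficient arrays are too few to split.

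The control groups, which share 1 slide, differed in few genes. Mmp12 was 16.9-fold higher in homozygous wild type than in heterozygous cells (10.68 ± 0.64 against 6.60 ± 0.71, SD, n = 3 each, limma adjusted p = 0.0169). Mmp8 was at least 6.32-fold higher and AA467197 at least 4.83-fold higher, and all 3 were also higher in deficient cells against both controls. Fdps, an enzyme of cholesterol synthesis, was 8.24-fold lower by its brightest probe and differed by -0.43 at the other, and it was higher by 2.40 in deficient than in homozygous wild type cells (adjusted p = 0.0393). These were the 4 genes called (780 at an unadjusted p under 0.05), and the count was 0 without homozygous wild type replicate 2 or 3 or heterozygous replicate 1 or 3 (525 to 1044 at an unadjusted p under 0.05) and 2 without heterozygous replicate 2. Camera called 11 lists, 9 higher and 2 lower. They included the monocyte, complement, lysosomal, transcription factor, matrix remodelling and cell cycle lists, in the same direction as in deficient cells against both controls. Of these, all but matrix remodelling and cell cycle lost the call in some fits that left out a control array. Proinflammatory cytokines (adjusted p = 0.000272), matrix remodelling genes (0.00173) and LXR-linked cholesterol efflux genes (0.00498, and 0.159, 0.0835 and 0.0556 without homozygous wild type replicate 1 or 3 or heterozygous replicate 3) were higher, and cholesterol synthesis (0.00151) and cell cycle genes (0.00173) lower. The smallest adjusted p with an estimated correlation was 0.195.

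**Figure D3:**
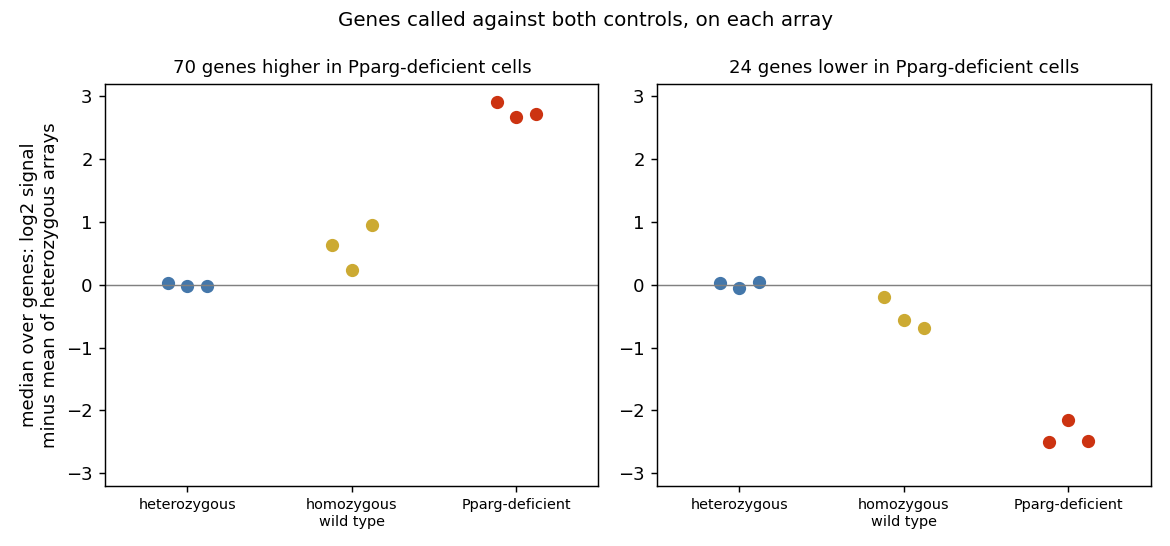
Median over the 70 genes called higher (left) and the 24 called lower (right) against both controls of each array's log2 signal minus the mean of the heterozygous arrays (y axis), 1 point per array in 3 groups (x axis). The genes were chosen by this comparison; the homozygous wild type arrays lie at 0.64, 0.24 and 0.95 on the left and the deficient arrays from 2.67 to 2.92.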

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

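The tests of the slide, of a share of deficient cells and of Lyz2 were chosen after the results were seen; the splits of the arrays were planned, and the background covariate was added after seeing the data, before its own result was seen. Probes without a gene symbol carry signal that the gene counts leave out: in a fit of all passing probes, 14 of 4669 unnamed probes passed the threshold between Pparg-deficient cells and both controls, 6 higher and 8 lower (0.3%, against 0.793% of named probes).

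The first pattern is the set of 94 genes called between deficient cells and both controls. With the 2 sides fitted alone, 2 of the 84 splits of the 9 arrays, the real one among them, gave at least as many genes as the real one. The real split gave 58 genes and the highest other 175, so the count leaves chance open. The split with 175 genes sets homozygous wild type replicate 1 with deficient replicates 1 and 2, the 3 arrays with the lowest median signal, and points to a structure of the samples along array background. With background level as a covariate all 94 genes kept their direction at a median ratio of 1.00 (quartiles 0.906 and 1.07). The covariate's slope comes from the spread within groups, and the genes were chosen partly by a small spread there. A ratio near 1.00 is thus favoured by the choice, so it does not decide whether background caused their differences. Only 32 stayed past the threshold. The median SE grew from 0.302 to 0.360 while the median size went from 2.27 to 2.17, but what ended the other calls was not tested. Slide and group cannot be told apart for any of the 94 genes, since no deficient array lies on the slide of the controls, so neither the 3 genes that were also called between the controls nor the same sign there of 76 of the other 91 decides it.

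For the single control groups the splits are too few for a share under 0.05. Against heterozygous cells 1 of 10 splits, the real one with 149 genes, gave as many, and the highest other gave 0. Against homozygous wild type cells 1 of 10 did, with 10 genes and 0. Between the controls all 10 did, with 0 genes in the real split (746 at an unadjusted p under 0.05) and 0 in the highest other.

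The second pattern is that, of the 94 genes, 79 differed between the controls in the direction of the deficient cells, but another split of the 6 control arrays gave 81, so it is not beyond what other splits give. With background level as a covariate the median difference between the controls over the 70 genes higher in deficient cells was 0.68, from 0.66. These genes were chosen in the same way as above, so this does not decide on background either. A candidate explanation is a share of deficient cells in the sorted homozygous wild type cells. Over the 129 genes called against heterozygous cells the best common share was 21%, but the mean squared z around it was 6.63, above the highest of 1000 simulations (1.45), and the simulations leave out how genes were chosen, so this stays open. A biological difference between mice of the 2 genotypes was not tested.

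The third pattern is Lyz2, the gene that drives the Cre. Each of the 3 heterozygous arrays had a Lyz2 probe above background and 0 of 6 homozygous arrays did. This is 1 of 84 choices of 3 arrays, but the pattern was defined after it was seen, so that count restates it and leaves chance open. The total number of probes above background was not lower on every homozygous array, since 5 of the 6 had at least as many as the lowest heterozygous array. That total covers all probes, so a loss among probes as dim as those of Lyz2 stays open. The same pattern was shown by 14 genes, against a median of 7 and up to 47 genes for other choices of 3 arrays, with 31 for the deficient arrays. A candidate explanation is a higher number of Cre alleles inserted in Lyz2 in the homozygous mice, but the labels give no number of Cre alleles and the signals are near background, so it was not tested.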

How the results depend on the processing

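The background covariate and the list tests without single arrays were chosen after seeing the data. The cause of the changes below was not tested unless named. The number of genes called against both controls (94) became 239 with normexp and offset 50, 276 without background correction, 142 with the strict filter, 151 probes with every probe tested (14 of them without a gene symbol), 308 with trend and robust variances, 58 with the 2 sides alone, 273 with the authors' normalized values and 35 with the background covariate; of these fits 87, 86, 93, 90, 93, 56, 84 and 32 of the 94 genes were shared. Against heterozygous cells (129) the counts were 292, 348, 230, 224 (probes), 375, 323 and 40 in the same fits other than the 2 groups alone, and 242 with array weights. Against homozygous wild type cells (24) they were 48, 67, 42, 38 (probes), 72, 10 and 63 in the same order up to the authors' values. Between the controls (4) they were 9 with offset 50, 15 without background correction, 7 with median scaling, 2 without normalization between arrays, 0 without a filter (1222 at an unadjusted p under 0.05), 45 with trend and robust variances, 0 with 2 groups alone (746) and 21 with the authors' values. Leaving out 1 array gave 22 to 99, 44 to 156, 7 to 28 and 0 to 6 genes; where a group keeps 2 arrays the fit pools the spread of all groups. Median scaling and no normalization moved the median of all genes against both controls to -0.20 and -0.29, and against heterozygous cells no normalization gave 76 higher and 41 lower.

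The replicate number as a block gave 58, 106, 19 and 2 genes. Same-numbered arrays did not all deviate together (correlations of deviations from -0.06 to 0.22), and not every array correlated best with its own number. Arrays of different number lay lower, from -0.26 to 0.16, so a structure along the replicate number is possible. The titles give the same numbered names to both homozygous groups, so a shared mouse is not settled. The block also joined each heterozygous array with the homozygous arrays of the same number, though their mice differ in genotype. A pairing of the 2 homozygous groups alone was not fitted. Under the block Lat2, C1qb, Syne2, Cidec, Siglecf, Marco, Rrm2, Ier3, Birc3 and Mmp8 were not called against both controls (adjusted p from 0.0501 to 0.092), nor Vnn3 and Wtip against homozygous wild type cells (0.0561), nor Mmp8 and AA467197 between the controls (0.0718 and 0.0661). Camera's lists called were 0 in all 4 comparisons with an estimated correlation, where 5, 7, 2 and 7 lists had an unadjusted p under 0.05. Against both controls (13) 8 were called with the background covariate, 7 of them shared. Against homozygous wild type cells (7) the number was 14 without background correction, 11 without normalization, 14 without a filter, 12 with every probe, 12 with trend and robust variances and 13 with the authors' values. Between the controls (11) it was 17 with median scaling, 17 without normalization and 6 with fry. Leaving out 1 array gave 10 to 14, 10 to 12, 4 to 7 and 6 to 13 lists. All other alternatives were within 1.5 times.

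Pparg passed the threshold against both controls with offset 50 (-1.32), without background correction (-1.11), with the strict filter (-1.70), with trend and robust variances (-1.70) and with the authors' values (-1.08), and adjusted p over all alternatives ran from 0.00488 to 0.257. Against heterozygous cells it passed in the same fits (-1.50, -1.27, -1.93, -1.93 and -1.22) and with array weights (-1.92) and 2 groups alone (-1.93). Without 1 array its differences were -1.92 to -1.50 against both controls, -2.06 to -1.78 against heterozygous cells, -1.91 to -1.09 against homozygous wild type cells and -0.81 to -0.02 between the controls. Direction reversed where another probe became the brightest: Colec12, higher by 2.89, gave -0.10, -0.061 and -0.087 with offset 50, without background correction and with the authors' values, and -0.35 to 2.90 over the fits without 1 array, and Papss2 gave -0.69 to 4.14 against both controls and -0.68 to 4.18 against homozygous wild type cells. Over all named genes other than Pparg, 868 values kept their direction and side of the threshold under the settings other than left-out arrays, 75 lost and 76 gained the call and 3 reversed, and without 1 array 525, 107, 6 and 7. The slide as a block was not run, since it changes nothing within 1 slide and cannot be fitted elsewhere. Signal over background limits 47 of the 94 genes to bounds in at least 1 group.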

Other observations

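The correlation of the first component and the genes of the next paragraph were chosen after their values were seen. Other lists held changes in few members between deficient cells and both controls. Apoe, a lipid carrier and LXR target, was 7.49-fold higher (limma adjusted p = 0.00676, ended without deficient replicate 1), while the cholesterol efflux list had a median of -0.20 and a mean of 0.01 and was not called (camera adjusted p = 0.752). Of 16 scavenger and phagocytic receptors Colec12 rose (at least 4.78-fold, with 1 of its 3 probes at -0.29; that probe was the brightest and not called without any 1 deficient array, and with offset 50, without background correction and with the authors' values the difference was -0.10, -0.061 and -0.087), Marco fell, and Trem2 and Mfge8 differed by 2.15 and 1.64 without passing, while the second probe of Mfge8 passed at 2.06 (list adjusted p = 0.175). Asns, an asparagine synthetase induced by amino acid stress, rose at least 2.78-fold among 17 genes of the unfolded protein response (0.0741). Camera did not call anti-inflammatory and alternative activation genes (0.0519), oxidative stress genes (0.199), interferon-stimulated genes (0.264), MHC class I presentation (0.349), fatty acid synthesis (0.175), oxidative phosphorylation (0.284) or glycolysis and hypoxia genes (0.953). Fry called higher the anti-inflammatory (adjusted p = 0.0131) and scavenger lists (0.0249) and called lower fatty acid synthesis (0.0249). The scavenger list had a median of -0.02 and a mean of 0.30.

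The cholesterol synthesis list had a median of 0.90 in deficient against homozygous wild type cells (1 of 10 members called), -0.82 between the controls (1 called) and 0.03 in deficient against heterozygous cells (0 called), with adjusted p = 0.349, 0.195 and 0.687 with an estimated correlation. Its members Mvd and Nsdhl went the other way, by -0.99 and -0.45 against homozygous wild type cells, without passing. Lyz1, a close paralog of Lyz2 whose probes may read both, differed by -3.23 between homozygous wild type and heterozygous cells at its brightest probe (limma adjusted p = 0.0953) and by 3.45 between deficient and homozygous wild type cells (adjusted p = 0.0443). At both of its other probes the arrays of the control groups overlapped. At 1 of these probes deficient replicate 3 (5.22) also lay below homozygous wild type replicate 2 (5.62). Itgam, which encodes the sorting marker CD11b, was above background on deficient replicate 1 alone, at 7.53.

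The first principal component of the 12246 genes (28.6% of the variance) followed the log2 median raw signal of the arrays, with Pearson's r = 0.95 (exact permutation p = 0.00019, adjusted 0.00076) and Spearman's rho = 0.917 (exact permutation p = 0.00131, adjusted 0.00262) over 9 arrays. Without the 2 arrays farthest from the median signal r was 0.943. Within the slide of the 6 control arrays r was 0.956 (exact permutation p = 0.0125, adjusted 0.0167) and rho 0.886 (exact p = 0.0333, adjusted 0.0333), but r was 0.368 without the 2 farthest arrays, so there the relation rests on those arrays. The slide of the 3 deficient arrays holds too few for a value. These 4 p-values form the family over which the Benjamini-Hochberg adjustment was made.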
